A study of Mus musculus with 6 samples.

How the data were processed

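RNA left after removal of ribosomal RNA was sequenced from outer hair cells of the mouse organ of Corti at E18.5. The cells carried a GFP-Cre allele at Insm1 and were purified by fluorescence-activated sorting, and the 6 libraries fall by label into 3 from Insm1-Het and 3 from Insm1-KO animals. Per the labels' protocols, complementary DNA was primed with random hexamers and amplified, fragments were about 200 bp long, and paired reads of 100 bp were sequenced. The labels do not say whether the libraries came from separate animals, pools or litters, so p-values measure only the spread between these samples, which may be technical.

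The authors deposited whole-number read counts per gene symbol, 1 file per library, and the counts were not normalized. Per the submitters' processing notes, Trimmomatic, STAR and HTSeq were used with the mouse genome build GRCm38 (mm10). Tool versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Each file held 23337 symbols in the same order and 0 blank or summary lines. The files listed 0 mitochondrially encoded genes, so the share of mitochondrial reads was not analysed here. Symbols were older names in part, and 23068 were matched to the RefSeq gene table of GRCm38 by symbol or synonym. Gene positions came from GENCODE release M21 on GRCm38, the build named in the submitters' notes. Without a stated strand setting, reads of genes with overlapping exons cannot be told apart. Among the genes named here this concerns Cbx7, Chrna10, Cnp, Ctbp2, Dll1, Egfl7, Fgfr3, Gfi1, Gnas, Hsp90b1, Ikzf2, Lhx3, Nefm, Nos1ap, Pdgfra, Pink1, Prox1, Tectb, Tomt, Ush1c and Xist, whose values are uncertain to that extent. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y have close copies on the X chromosome, so their counts depend on how reads of near-identical copies were assigned.

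Everything that follows was computed from the deposited counts. Genes were kept by filterByExpr by genotype (minimum count 10, minimum total 15), which left 11714 genes; the removed genes held 0.274% of all counts. Libraries were scaled by TMM. Genotypes were compared with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest with the defaults of the installed version, genotype as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F, and intervals are 95% intervals from it. Expression values are CPM, the counts of a gene scaled to a common total by the library total times its TMM factor, given as mean ± SD with n = 3 per genotype. Log2 CPM for correlations, principal components and gene set tests used a prior count of 2. Where all 3 libraries of a genotype were at 0, the fold was computed against a floor of 3 counts over the group and is a lower bound. Intervals of fold changes include the spread between libraries. Floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

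Before the data were examined, 24 gene lists were fixed: inner hair cell, outer hair cell, general hair cell, hair bundle and mechanotransduction, synapse and neurotransmission, secretory granule and neuroendocrine, neurogenic transcription factors, Notch pathway, FGF pathway, supporting cell, greater epithelial ridge, spiral ganglion neuron, Schwann cell and glia, melanocyte and stria, mesenchyme, erythroid, endothelial, immune, cell cycle, p53 targets and apoptosis, dissociation stress, unfolded protein response, mitochondrially encoded and sex-linked. The lists came from general knowledge of the field, which may include work on Insm1 itself, so their direction is not fully independent evidence. Each list was counted over all genes and adjusted over the list alone. The adjustment over a list alone was not corrected for the number of lists, so passing it is weaker evidence than passing over all genes. The 18 lists with at least 5 tested members, leaving out the sex-linked list, were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, each adjusted over the 18 lists.

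Genes to be named were set by a rule fixed at the same time: Insm1; up to 10 rises and 10 falls past the threshold without overlap of the genotypes and with a mean of at least 5 CPM; members of the inner and outer hair cell lists past the threshold and the 2 most abundant that were not; and for each other list the members past the threshold or the most abundant. Genes named outside the rule are marked as chosen after their values were seen, and 1 such gene is not reported here.

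The alternatives were DESeq2, limma-voom with and without sample quality weights, median-ratio, upper quartile and library-size scaling, no filter, a filter at 5 CPM in 3 libraries, removal of structural RNA genes, a robust dispersion fit, the replicate number as a block, stricter thresholds (0.01, or 0.05 with an absolute log2 fold change of at least 1) and leaving out each library in turn. The fixed plan named no form of the quasi-likelihood fit. A first draft used the newer form, which called 1 gene, Brip1; the default of the installed version, which called 0, was then set as the main form, after both counts had been seen. The newer form, alone and with the block, is thus an alternative added after the data were seen, as is camera with an estimated correlation for 2 list calls that arose with 1 library left out. Het and KO libraries share replicate numbers in the labels, and the labels do not say that a number marks a shared litter or day. The main comparison therefore had no block.

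The total count per library ran from 7705177 to 12427039. With these counts, the median half-width of the 95% interval of a log2 fold change was 1.40 over all tested genes, 0.642 for genes with a mean of at least 100 CPM and 3.34 for genes under 10 CPM. The comparison was tested on simulated data built from the means and library sizes of the 11714 genes. In each of 10 runs, 200 genes with a mean of at least 5 CPM were changed. The test recovered 41.5% of 4-fold, 76.9% of 16-fold and 90.5% of 64-fold changes, and 54 of 1444 calls were false. Changes in lower genes and a library that stands apart from the others were not simulated. Runs with fewer changed genes were not simulated either. The adjustment over all genes is stricter where few genes change, so the shares recovered may be too high for such data. In simulated lists of 8 genes, camera found 20 of 20 lists shifted 4-fold and 0 of 20 unshifted lists. This was at an unadjusted p under 0.05 and with every member of a shifted list raised. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.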

Results

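RNA was profiled in outer hair cells, the electromotile sensory cells of the cochlea, sorted from Insm1-Het and Insm1-KO mice at embryonic day E18.5. Insm1 encodes a zinc-finger transcription factor that is transiently expressed in nascent outer hair cells, and the series addresses whether outer hair cells take on inner hair cell identity without it. The 3 Het libraries held 11738214, 10721902 and 12427039 counts and the 3 KO libraries 9259736, 7705177 and 9748629. Between 12126 and 13763 genes were detected per library, and Rn45s, the precursor of ribosomal RNA, took 1.89% to 3.09% of the counts.

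Insm1 itself lies on the plus strand of chromosome 2, from 146221921 to 146225020 on GRCm38, and is annotated as 1 exon with the coding sequence from 146222266 to 146223828 between untranslated parts on both sides. Its level was 109.3, 116.2 and 69.2 CPM in the Het libraries and 78.7, 60.3 and 18.7 CPM in the KO libraries, or 98.3 ± 25.4 against 52.6 ± 30.7 CPM (SD, n = 3). The log2 fold change was -0.90 with a 95% interval from -1.97 to 0.17, and it was -0.49 without KO replicate 3. This difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.938). An exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest value that 3 against 3 libraries allow. Transcript from Insm1 was thus counted in all KO libraries, and KO replicate 1 lay above Het replicate 3. The labels do not say which part of the gene is deleted, and reads from a part left in place would still be counted, so this level checks the genotype labels only in part.

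Among genes known from inner hair cells, Brip1, Tbx2 and Rprm were higher in all 3 KO libraries than in any Het library. Brip1, a DNA helicase of the Fanconi anaemia pathway (chromosome 11, 86058138 to 86201193), averaged 2.14 ± 3.29 CPM in Het and 195.5 ± 195.9 CPM in KO libraries (SD, n = 3), with 76.8, 88.0 and 421.5 CPM in KO replicates 1, 2 and 3. Its log2 fold change was 6.49 (SE 1.16), with 5.26 without KO replicate 3 and 9.52 without Het replicate 3 as the lowest and highest values when 1 library was left out. Tbx2, a T-box transcription factor of inner hair cells (chromosome 11, 85832551 to 85841948), averaged 0.296 ± 0.293 against 9.41 ± 8.47 CPM, with 4.06, 19.2 and 5.01 CPM in KO replicates 1, 2 and 3. Its log2 fold change was 4.92 (SE 1.62), and 3.89 without KO replicate 2 to 6.06 without Het replicate 3. Rprm, the p53-responsive cell cycle inhibitor Reprimo (chromosome 2, 54084093 to 54085552), averaged 209.6 ± 22.0 against 372.7 ± 122.6 CPM, a log2 fold change of 0.83 (SE 0.27), and 0.54 without KO replicate 2, the lowest value with 1 library left out. Of the 8 tested members of the inner hair cell list, 3 passed when adjusted over the list alone and 0 passed over all genes, where Brip1 had an adjusted p of 0.415 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Brip1 did pass over all genes in 4 alternatives of the same test with Benjamini-Hochberg adjustment: the replicate block (adjusted p = 0.000504), no filter (adjusted p = 6.45e-34), and the newer form of the fit, alone (adjusted p = 0.00449) or with the block (adjusted p = 0.000778). The far smaller value with no filter came without a larger fold, since the log2 fold change of Brip1 was 6.49 there too. It is therefore not taken as stronger evidence. It did not pass under DESeq2, limma-voom or a robust dispersion fit (adjusted p = 0.102, 0.879 and 0.793 with Benjamini-Hochberg adjustment), nor without any 1 library. The other 5 tested members did not pass either way. Otof, the calcium sensor of hair cell exocytosis, was at 448.2 ± 40.3 CPM in Het and 479.2 ± 89.1 CPM in KO libraries, with a 95% interval of the log2 fold change from -0.37 to 0.56. Nhlh1, a basic helix-loop-helix factor, was at 374.6 ± 97.7 and 320.6 ± 64.9 CPM, with an interval from -0.78 to 0.33. Fgf8, the growth factor that inner hair cells secrete, fell below the filter with 0 counts in each Het library and 87, 0 and 42 counts in the KO libraries. Slc17a8, the vesicular glutamate transporter of inner hair cells, had 6, 0 and 15 counts in Het and 18, 0 and 0 counts in KO libraries. Fgf8 and Slc17a8 were chosen after their values were seen.

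The list as a whole had a median log2 fold change of -0.02 and a mean of 1.17, and camera placed it upward without passing (adjusted p = 0.41 by camera with Benjamini-Hochberg adjustment, adjusted p = 0.696 with an estimated correlation). The median thus differed in sign from the mean and the test. Without Het replicate 1, 2 or 3, Brip1 was the 1 gene left past the threshold adjusted over the list alone; without KO replicate 2 there were 2 genes, and without KO replicate 1 or 3 there were 3. With the replicate block Brip1 was also the 1 gene left: the log2 fold change of Tbx2 was 4.83 (SE 1.99) and that of Rprm 0.78 (SE 0.28), each with a smaller fold and a larger SE than without the block. In the newer form of the fit with the block all 3 passed, Tbx2 and Rprm at an adjusted p of 0.0437 over the list in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 passed 3 members adjusted over the list alone, and limma-voom passed 2. The list may have been shaped by knowledge of Insm1 mutants, so its count is not fully independent evidence. Nor was the adjustment over the list alone corrected for the number of lists.

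**Figure D1:**
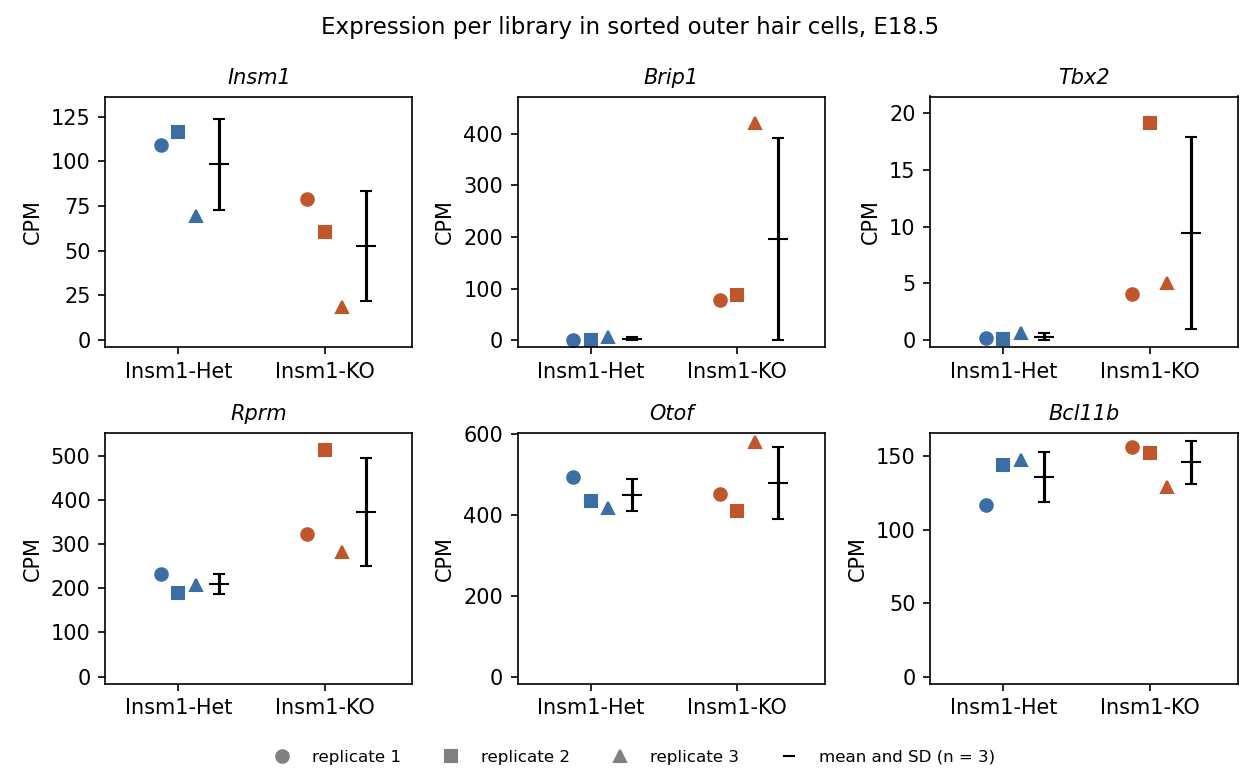
CPM (y axis, linear) of 6 genes in the 3 Insm1-Het and 3 Insm1-KO libraries (x axis); each symbol is 1 library, its shape the replicate number, and the bar shows mean and SD, stopping at 0 where the SD exceeds the mean. Brip1 lay between 76.8 and 421.5 CPM in KO libraries and averaged 2.14 CPM in Het libraries, while Insm1, Otof and Bcl11b overlapped between genotypes.

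No single gene of outer hair cell identity passed, higher or lower. Bcl11b, a zinc-finger factor, was at 135.8 ± 16.9 CPM in Het and 145.7 ± 14.7 CPM in KO libraries (SD, n = 3). Slc26a5, the motor protein prestin, was at 38.1 ± 13.1 and 33.4 ± 14.6 CPM, and Ikzf2, the regulator Helios, at 18.8 ± 20.7 and 40.7 ± 32.1 CPM; these 3 genes were chosen after their values were seen. The 2 most abundant members were Strip2, listed as Fam40b, at 281.9 ± 45.1 and 201.6 ± 11.3 CPM (95% interval of the log2 fold change -1.01 to 0.04), and Chrna10, a subunit of the efferent acetylcholine receptor, at 156.1 ± 14.8 and 185.1 ± 33.6 CPM (-0.34 to 0.83). Ocm, the calcium buffer oncomodulin, also chosen after its values were seen, had 0 counts in every Het library and 15, 22 and 33 counts in the KO libraries, at least 32.2-fold higher.

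Of the 13 members of the outer hair cell list, all tested, 0 passed over all genes. Adjusted over the list alone, 0 passed by edgeR, DESeq2 and limma-voom. By edgeR 1 member, Ocm, had an unadjusted p under 0.05. The median log2 fold change was 0.10, and camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.492 (adjusted p = 0.835 with an estimated correlation). Its direction, upward, turned downward under the filter at 5 CPM in 3 libraries (adjusted p = 0.919). The list did pass fry's test for change in either direction (adjusted p = 0.00185 with Benjamini-Hochberg adjustment), which compares its members with no other genes.

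**Figure D2:**
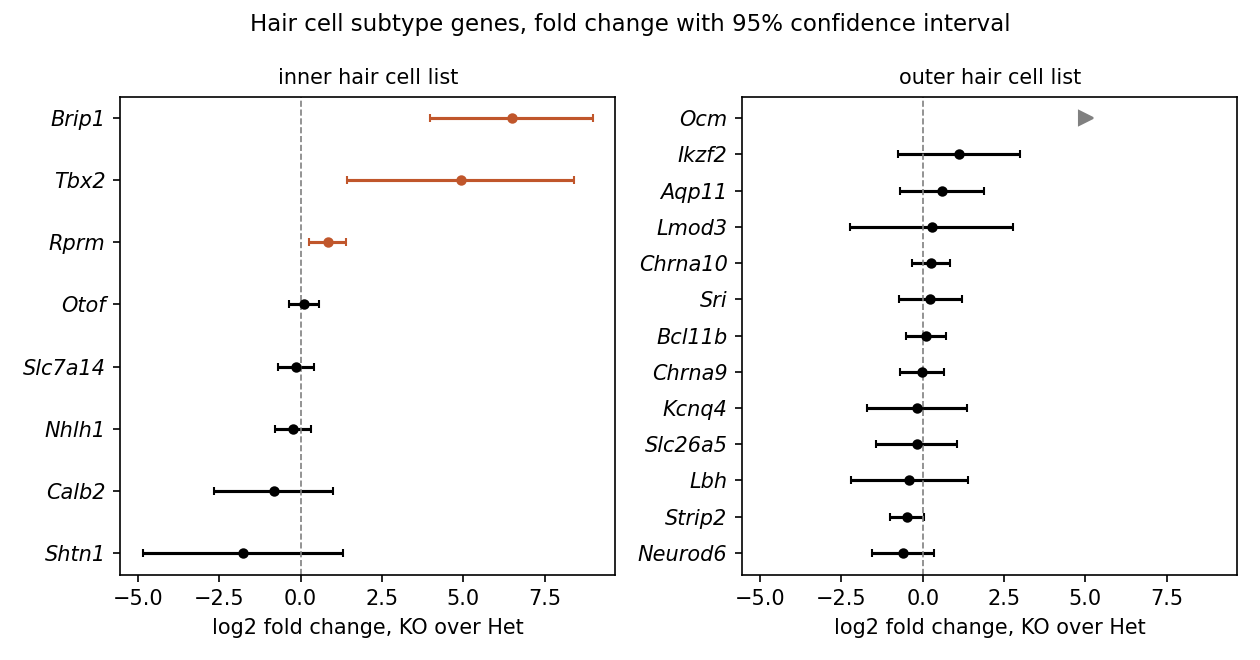
Log2 fold change of KO over Het (x axis) for the tested members of the inner and outer hair cell lists (y axis), with 95% confidence intervals; orange marks genes past the threshold adjusted over the list alone, and the grey triangle at Ocm is a lower bound. Brip1, Tbx2 and Rprm passed. Ocm did not pass, and its fitted interval, not drawn, ran from 2.17 to 13.4. The intervals of all other members included 0.

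The most abundant tested member of 7 further lists was counted in every library. Gnas, Runx1t1, Jag2 and Fgfr3 stood for the secretory granule, neurogenic factor, Notch and FGF lists. Fgfr3 was also on the supporting cell list, so these genes do not by themselves mark hair cells. Myo6, an unconventional myosin of hair cells, was at 5077 ± 182.6 CPM in Het and 4990 ± 166.9 CPM in KO libraries (SD, n = 3), with a 95% interval of the log2 fold change from -0.27 to 0.22. Ptprq, a phosphatase of the stereocilia, was at 2119 ± 255.4 and 2255 ± 288.7 CPM. Rims2, an active zone scaffold, was at 602.4 ± 58.9 and 663.7 ± 72.9 CPM. Gnas, the stimulatory G protein subunit, was at 1060 ± 96.4 and 941.7 ± 113 CPM, and Runx1t1, a transcriptional corepressor, at 735.2 ± 146.2 and 1076 ± 311.6 CPM. Jag2, a Notch ligand of hair cells, was at 382.6 ± 70.8 and 299.7 ± 125.5 CPM, and Fgfr3 at 264.4 ± 22.5 and 237.5 ± 19.1 CPM. None of these 7 genes passed.

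By edgeR's test, 0 members passed over all genes and 0 passed adjusted over the list alone in the general hair cell list (20 tested), the hair bundle list (29), the synapse list (20), the secretory granule list (14), the neurogenic factor list (10), the Notch list (19) and the FGF list (14). At an unadjusted p under 0.05 these lists held 3, 3, 1, 2, 1, 1 and 1 members, and DESeq2 and limma-voom also passed 0 in each. Their adjusted p values by camera with Benjamini-Hochberg adjustment were 0.41, 0.492, 0.437, 0.993, 0.492, 0.41 and 0.41. The general hair cell list reached 1 member adjusted over the list alone without KO replicate 1 and the FGF list reached 2 without KO replicate 2 and 3 with no filter; the FGF list had an adjusted p of 0.0461 by camera with Benjamini-Hochberg adjustment without Het replicate 3 (adjusted p = 0.714 with an estimated correlation, chosen after the data were seen). In the secretory granule list the median was -0.22 while the mean was 0.01 and the test pointed upward. For change in either direction, fry passed 3 lists with Benjamini-Hochberg adjustment: the secretory granule list (adjusted p = 0.00143), the outer hair cell list (adjusted p = 0.00185) and the inner hair cell list (adjusted p = 0.00739). This test asks whether members of a list change at all and compares them with no other genes.

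Markers of other cell types of the cochlea were measured in the same libraries. Prox1, a supporting cell factor, was at 453.5 ± 73.3 CPM in Het and 600.4 ± 126.2 CPM in KO libraries (SD, n = 3), and Tectb, a tectorial membrane protein, at 935.2 ± 209.8 and 995.8 ± 251.8 CPM. Nefm, a neurofilament of neurons, was at 532.1 ± 84.6 and 662.9 ± 274.5 CPM, and Pdgfra, a receptor of mesenchyme, at 285.5 ± 62.0 and 260.6 ± 80.2 CPM. Cnp, a glial myelin protein, was at 120.2 ± 32.1 and 132.1 ± 15.95 CPM, and Laptm5, a lysosomal protein of leukocytes, at 104.7 ± 18.1 and 71.5 ± 55.9 CPM. Kcnj10, a potassium channel of the stria, was at 6.99 ± 5.66 and 18.9 ± 10.9 CPM, and Egfl7, an endothelial factor, at 11.4 ± 8.09 and 8.26 ± 7.09 CPM. None of these 8 genes passed.

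In the supporting cell (19 tested), greater epithelial ridge (11), spiral ganglion neuron (15), Schwann cell and glia (6), mesenchyme (8), endothelial (4), melanocyte and stria (1) and immune (1) lists, edgeR passed 0 members over all genes and 0 adjusted over the list alone. The counts at an unadjusted p under 0.05 were 5, 1, 1, 1, 0, 0, 0 and 0. DESeq2 passed 2 supporting cell members and 1 glial member adjusted over the list alone, limma-voom passed 0, and limma-voom with quality weights passed 1 immune member. With no filter edgeR passed 2 ridge members and 1 immune member, and in the newer form, with or without the block, 1 glial member. Without KO replicate 1 the neuron list had 1 member, without KO replicate 2 the ridge and glial lists had 1 each, and without KO replicate 3 the immune list had 1. The erythroid list had 0 tested members and the mitochondrially encoded list 0 genes in the files. The neuron list had the lowest median, -0.83, with 11 of 15 members below 0. It did not pass by camera with Benjamini-Hochberg adjustment (adjusted p = 0.249, or adjusted p = 0.696 with an estimated correlation); without Het replicate 1 its adjusted p was 0.00753 (adjusted p = 0.708 with an estimated correlation, also chosen after the data were seen). The lists for supporting cells, ridge, glia and mesenchyme had adjusted p values of 0.677, 0.917, 0.864 and 0.512 by the same test. With the estimated correlation, as with the preset, camera passed 0 of the 18 lists.

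Zmat3, a p53 target that binds RNA (chromosome 3, 32334792 to 32366014), was at 349.7 ± 29.6 CPM in Het and 591.5 ± 105.2 CPM in KO libraries (SD, n = 3), a log2 fold change of 0.76 (SE 0.21). It was the 1 member of the 11 tested p53 targets that passed adjusted over the list alone, and 0 passed over all genes; without Het replicate 1, 2 or 3 or without KO replicate 2 or 3, with library-size scaling, at an adjusted threshold of 0.01 and at an absolute log2 fold change of at least 1, the count was 0. The replicate block also ended the call of Zmat3, in the default and the newer form of the fit: with the block its log2 fold change was 0.75 (SE 0.23) in both forms. In the default form the fold was slightly smaller and the SE larger than without the block, and in the newer form the total degrees of freedom also went from 19.5 to 12. Egr1, an immediate early factor, was at 530.6 ± 163.9 and 679.5 ± 132.6 CPM, Hsp90b1, a chaperone of the endoplasmic reticulum, at 1638 ± 201.2 and 1441 ± 395.5 CPM, and Mcm6, a replication helicase, at 42.1 ± 21.3 and 53.5 ± 20.1 CPM. Of the dissociation stress (13 tested), unfolded protein response (13) and cell cycle (14) lists, 0 members passed over all genes and 0 adjusted over the list alone by edgeR, DESeq2 and limma-voom, with 0, 1 and 0 at an unadjusted p under 0.05. In the dissociation stress list 12 of 13 members lay above 0. The camera test with Benjamini-Hochberg adjustment gave adjusted p values of 0.41, 0.41, 0.752 and, for the p53 targets, 0.917.

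Of the sex-linked genes, the Y-linked Ddx3y was at 25.1 ± 13.6 CPM in Het and 3.89 ± 1.22 CPM in KO libraries, and Xist, the RNA that silences an X chromosome, at 407.1 ± 159.5 and 616.5 ± 144.6 CPM (SD, n = 3). Ddx3y passed adjusted over the list alone (1 of 5 tested; 0 over all genes; 2 under DESeq2 and 4 under limma-voom). The count was 0 at an adjusted threshold of 0.01 and without Het replicate 1, 2 or 3 or KO replicate 2. It was 4 with no filter or with the replicate block, 3 in the newer form with the block, and 2 in the newer form alone, with upper quartile or library-size scaling and without KO replicate 1 or 3.

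Across all 11714 tested genes, no gene met the threshold, and the genes with the smallest p are given as values chosen after they were seen. Higher in all 3 KO libraries, after Brip1, were Rin3, a guanine nucleotide exchange factor of Rab5-type endosomal transport, at 6.97 ± 4.71 against 96.5 ± 87.3 CPM, and Sez6l, a neuronal membrane protein, at 9.22 ± 0.988 against 71.8 ± 38.8 CPM (SD, n = 3). With 1 library left out the log2 fold change of Rin3 ran from 2.732 to 4.467 and that of Sez6l from 2.573 to 3.327. Pink1, the mitochondrial kinase of mitophagy, was at 7.89 ± 3.73 against 57 ± 22.5 CPM. Nhs, Car13, Lpar3, Lrrn1 and Nos1ap were also among the 10 with the smallest p; Nhs and Nos1ap reached 213.7 and 142.6 CPM in KO replicate 3. Lower in all 3 KO libraries were Cbx7, a Polycomb chromobox protein, at 27.9 ± 32.3 against 0.0712 ± 0.123 CPM, and Epha5, an ephrin receptor, at 15.1 ± 13.8 CPM against 0 counts in KO, at least 131-fold lower. That bound holds for the Het mean only, since the Het libraries held 29.6, 2.25 and 13.4 CPM of Epha5. Tbc1d19 was at 153.3 ± 28.6 against 57.7 ± 14.99 CPM, Sgk3, a serum and glucocorticoid regulated kinase, at 18.9 ± 2.86 against 1.13 ± 0.502 CPM, and Pik3cb, a catalytic subunit of phosphoinositide kinase, at 56.3 ± 11.3 against 14.6 ± 2.58 CPM. Ribc1, Exd1, Pdik1l, Tmem170b and Arhgap32 completed the 10 with the smallest p in that direction. Both sets of 10 were limited to genes without overlap of the genotypes and with a mean of at least 5 CPM in 1 genotype. Symbols of clones, predicted genes and pseudogenes were left out. The clone 5930403L14Rik had a smaller p than any of the 10 lower genes, at 20.9 ± 16.7 CPM in Het and 0 counts in KO libraries, at least 181-fold lower. This bound, too, holds for the Het mean only, since the Het libraries held 5.70, 18.2 and 38.8 CPM of the clone.

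By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes passed and the smallest adjusted p was 0.415. At an unadjusted p under 0.05 there were 626 genes, 374 higher and 252 lower in KO libraries, where 586 are expected by chance; without KO replicate 1 there were 1012, and without KO replicate 3 303 of 682 were higher. DESeq2 called 26 genes (16 higher, 10 lower), limma-voom called 0 with or without quality weights, and edgeR without a filter on low counts called 67. The replicate block and the newer form of the fit, alone or with the block, called 1 gene each, Brip1. The 2 genotypes did not overlap in 1310 genes, 11.2% of those tested, and chance gives 10%. The biological coefficient of variation was 0.72.

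The libraries did not group by genotype. Pearson correlations of log2 CPM ran from 0.80 to 0.84 among Het libraries, from 0.761 to 0.812 among KO libraries and from 0.746 to 0.841 between genotypes, across genes that are not independent replicates. The first principal component, 33.4% of the variance, set KO replicate 3 (151.3) apart from the other 5 libraries (-37.84 to -22.73). KO replicate 3 also held the highest values of Brip1, Rin3, Nhs and Nos1ap and the lowest of Insm1.

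**Figure D3:**
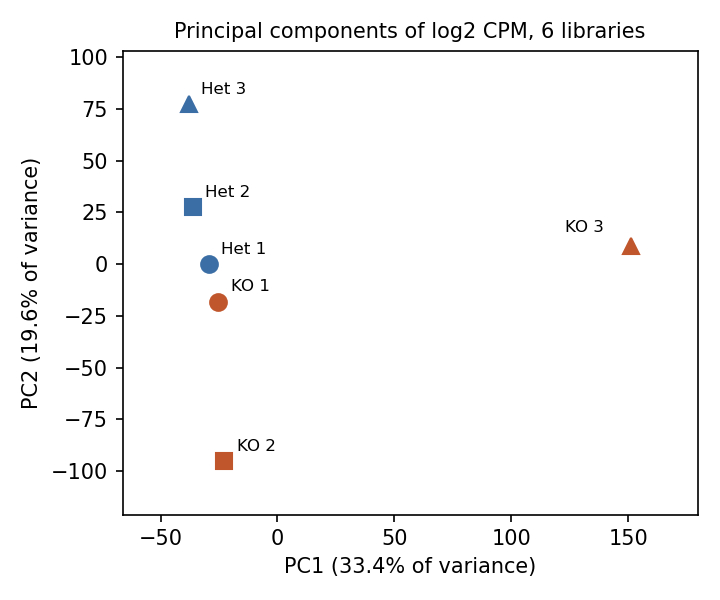
First and second principal components of log2 CPM over the 11714 tested genes, with the share of variance on each axis; each symbol is 1 library, blue for Insm1-Het and orange for Insm1-KO. KO replicate 3 stood at 151.3 on the first component, and the other 5 libraries lay between -37.84 and -22.73.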

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

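The newer quasi-likelihood fit, with and without the block, and the estimated correlation with 1 library left out were chosen after the data were seen; the other alternatives were fixed before. Of 1859 comparisons of a direction or call across genes and gene set tests, 1787 kept direction and side of the threshold, 33 came to pass it and 39 turned direction. The cause was not tested where none is named. The count of genes past the adjusted threshold, 0 by edgeR, was 26 under DESeq2, 67 with no filter on low counts, 1 under the newer fit and 1 under the newer fit with the replicate block; it was 0 with any 1 library left out. The adjusted p of Brip1 (edgeR quasi-likelihood, Benjamini-Hochberg) ranged from 6.45e-34 with no filter, which came without a larger fold, to 0.988 without Het replicate 1. Genes at an unadjusted p under 0.05 numbered 1137 of 15648 tested with no filter, against 626 of 11714 in the main fit. They numbered 972 under the newer fit and 462 to 1012 with 1 library left out. Members of the inner hair cell list passing alone were 1 at an adjusted threshold of 0.01 and 1 to 3 with 1 library left out. The replicate numbers showed no clear pairing of the libraries. Deviations of same-numbered libraries correlated at 0.0101, 0.0073 and 0.0144, and those of other Het and KO pairs at -0.0274 to 0.0227. Het replicate 1 correlated best with KO replicate 2. With 3 libraries per genotype, values this small do not exclude a small shared effect of litter or day. With the replicate block 1 gene, Brip1, was called and 1 inner list member passed. The median correlation of KO replicate 3 with the other libraries, 0.761, was 0.863 with no filter and 0.728 with the filter at 5 CPM, which change the genes compared. Set tests turned direction, never past the threshold, for the secretory granule list under fry (0.899), upper quartile scaling (0.958), library size only (0.933), no filter (0.755) and the replicate block (0.954), for the neurogenic list with no filter (0.464), and under the 5 CPM filter for the outer hair cell (0.919), greater epithelial ridge (0.805), cell cycle (0.919) and p53 (0.878) lists. With quality weights the log2 fold change was 0.034 for Pdgfra and -0.016 for Otof. With 1 library left out, some adjusted p values belonged to a turned direction, within the ranges 0.673 to 0.98 for the secretory granule list, 0.396 to 0.995 for supporting cells, 0.471 to 0.77 for the ridge, 0.744 to 0.963 for glia, 0.241 to 0.883 for mesenchyme, 0.543 to 0.995 for the cell cycle and 0.744 to 0.846 for p53 targets. Log2 fold changes near 0 crossed it in the same way: Nefm -0.066 to 0.49, Nhlh1 -0.35 to 0.0067, Ptprq -0.012 to 0.19, Pdgfra -0.34 to 0.10, Otof -0.054 to 0.21, Cnp -0.073 to 0.28, Egfl7 -1.24 to 0.30, Tectb -0.12 to 0.30, Myo6 -0.055 to 0.0036, Bcl11b -1.14e-05 to 0.19 and Slc26a5 -0.49 to 0.12. Depth limits the low genes, since 3 counts stand for 0.237 to 0.391 CPM.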

Other observations

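The tests of Brip1, Tbx2 and Rprm without KO replicate 3 and against inner hair cells in the sort were chosen only after the result was seen, as were the values of KO replicate 3 for SD and rho in genes of at least 100 CPM, the spread within cell type lists and the summed levels of lists. In the general hair cell, hair bundle and synapse lists 7 genes that did not pass were higher in every KO library than in any Het library, and 4 were lower. These lists had 20, 29 and 20 tested members, some of them shared. Over all tested genes 11.2% did not overlap between genotypes, and chance gives 10%, so several such genes are expected in these lists. Among the 7 higher genes were Tmc1 and Tmc2, the mechanotransduction channel genes. Tmc1 was at 4.15 ± 4.76 CPM in Het and 25.5 ± 5.73 CPM in KO libraries (SD, n = 3), a log2 fold change of 2.61 (SE 1.04). With 1 library left out it ran from 2.085 to 4.102. Tmc2 was at 40.7 ± 12.5 and 85.9 ± 32.7 CPM. Atoh1, the factor that initiates hair cell fate, was at 433.7 ± 20 and 676.7 ± 169.6 CPM, and Barhl1, a homeobox factor of hair cells, at 162 ± 39.2 and 284.2 ± 127.9 CPM. Cplx1, a complexin of the release machinery, was at 36.2 ± 4.09 and 82.4 ± 15.7 CPM, and Dll1 and Ctbp2 completed the 7. The 4 lower genes were Lhx3, a LIM homeobox factor, at 111.8 ± 16.05 and 72.4 ± 10.01 CPM, Gfi1, a zinc-finger repressor, at 184.6 ± 5.35 and 140.9 ± 29.7 CPM, Tomt, a methyltransferase, at 384.6 ± 37.3 and 287.2 ± 49.9 CPM, and Ush1c, the scaffold harmonin, at 61.99 ± 10.4 and 40.4 ± 12.96 CPM. Of other lists, Cadps and Cadps2, which prime dense-core vesicles, went apart, with Cadps at 6.25 ± 2.81 and 23.9 ± 6.36 CPM and Cadps2 at 283.8 ± 48.1 and 165.8 ± 55.1 CPM. Lfng, a modifier of Notch, was at 23.4 ± 2.25 and 70.2 ± 48.7 CPM, with 126.4 CPM in KO replicate 3, and Gjb2, the gap junction protein of supporting cells, at 33.0 ± 19.1 and 6.22 ± 1.86 CPM. These genes were chosen after their values were seen, and none passed over all genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p among all genes 0.415).

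The summed level of 4 Y-linked genes was 115.7 ± 28.4 CPM in Het and 36.9 ± 31.1 CPM in KO libraries (SD, n = 3). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allow. Every KO library (15.9 to 72.7 CPM) lay below every Het library (85.0 to 141.1 CPM), and Xist was counted in all libraries (228.3 to 758.2 CPM). A difference in the sex of the source animals can therefore not be told apart from genotype.

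Higher Brip1, Tbx2 and Rprm in KO libraries is the pattern nearest to the question of the series. KO replicate 3 as the only source is argued against, since KO replicates 1 and 2 also lay above every Het library for all 3 genes. Without KO replicate 3 all 3 genes passed adjusted over the list alone. For Tbx2 and Rprm this was near certain, since KO replicate 2 held their highest values (19.2 and 512.2 CPM). For Brip1 it was foreseeable too, since KO replicates 1 and 2 held 76.8 and 88.0 CPM against at most 5.93 CPM in Het libraries. The test without KO replicate 3 thus adds little to these values. Without KO replicate 2 the log2 fold changes of Tbx2 and Rprm were 3.89 and 0.54, and not all 3 genes passed. A change shared by the whole chromosome 11 neighbourhood, where Tbx2 and Brip1 lie 216 kb apart, is argued against: 23 neighbours within 1 Mb had a median log2 fold change of 0.016 (SD 1.16), at percentile 51.3 of random sets, while a change limited to a few genes stays open, since Prr11 (4.05) and 1200011M11Rik (1.18) were higher on average at an unadjusted p under 0.05. Inner hair cells in the KO sort stay open, since 0 of the 5 other members that were low in Het libraries were above every Het library in all 3 KO libraries, yet Fgf8 was so in 2 of them and Slc17a8, Atp2a3 and Cabp2, chosen after their values were seen, held at most 18 counts in any library. The 10 splits of the 6 libraries are too few for a share under 0.05 (real value 3 genes, as large in 1 split, highest other 0), and the genotype stays open as untested.

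KO replicate 3 stood apart from the other 5 libraries, and apart from cells of another type no biological explanation was tested. Low depth or genes near the floor are argued against, because over 2517 genes of at least 100 CPM its median correlation was 0.743 against 0.866 to 0.888 for the others, and its deviations had an SD of 0.692 against 0.349 to 0.422. A less complex library stays open, since this comparison does not measure complexity. With all libraries thinned to 7705177 counts, KO replicate 3 had the fewest detected genes (12018 against 12545 to 13587). Cells of another type stay open: the highest median deviation of a list with at least 5 tested members was 0.515 (greater epithelial ridge), under the bound of 1 set before, but its members had an SD of 1.77 and so decide nothing, as do the 4 tested endothelial genes (median 1.96, SD 3.19), the 15 of the neuron list (median -1.62, SD 1.68) and the 1 stria gene (1.97). Summed levels did not settle it. KO replicate 3 held the highest of all libraries for supporting cells (3357 CPM against 2062 to 2480), ridge (2759 against 1489 to 2739) and stria (42.6 against 5.06 to 23.6). The same held for general hair cell genes (15960 against 12960 to 15000). Its neuron sum (2145 against 1805 to 2465) and endothelial sum (34.1 against 7.74 to 41.7) lay within the others. GC content or transcript length is argued against as the whole cause: the larger rho across genes was 0.0853, and 0.182 in genes of at least 100 CPM, where Het replicate 1 reached -0.203 for length without standing apart.

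More genes were at 0 in every KO library while present in every Het library at 5 counts or more (26) than the reverse (3). Shallower KO libraries are argued against as the whole cause, since after thinning the counts were 20 and 4, a ratio of 5. The splits are too few for a share under 0.05. The real difference was 23, as large in 3 of 10 splits, and the highest other was 25. After thinning the real difference was 16, and other splits that mix the genotypes reached 20 and 23. The absence of Insm1 stays untested as a reason.

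For the other counts the 10 splits are again too few for a share under 0.05. Genes past the adjusted threshold numbered 0 in the real split and at most 0 in the others, as large in 10 of 10; genes at an unadjusted p under 0.05 numbered 626, as large in 1, with 623 in the highest other. Lists past fry's test for change in either direction numbered 3, as large in 1, with 1 in the highest other. Lists past camera went the other way, with 0 in the real split and 3 in the highest other.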
